A study of Homo sapiens with 17 samples.

How the data were processed

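RNA of NKYS cells was measured on 17 arrays, per the labels' protocols after electroporation of siRNAs or plasmids, extraction with TRIzol and a column, and biotin labelling with Nugen kits from 100 ng of total RNA. The deposited table holds linear signal intensity for 28869 probe sets. How the authors corrected the background, normalized the arrays and summarised probes is not given in the sources used here, and the intensities were used as deposited, after log2. The interquartile range of log2 intensity was 2.265 to 2.33 on the siRNA arrays and 1.79 to 2.183 on the plasmid arrays. Arrays carry no count of reads, so that the number of arrays sets the precision.

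Probe sets were named through the platform annotation, in which 19310 have 1 gene symbol, 1752 have several and 7807 have none. Only those with 1 symbol were named, and the probe set with the highest mean over all arrays stood for each of 18377 genes; 685 genes had more than 1. Gene identifiers were set against the RefSeq table of GRCh38.p14, which changed 0 symbols; no coordinates are printed because the files carry none. Genes whose mean over the arrays of a fit lay under the 30th percentile of all probe sets were left out, except JAK3 and EZH2.

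Groups were taken from the titles and the transfection fields. The labels do not say whether arrays of a group came from separate cultures, so that p-values measure the spread between these arrays, which may be technical. No array repeated another. On the 3 set 2 arrays with a full-length EZH2 plasmid, the titles name Y244D, Y244A and WT. Their transfection fields name wild type, MtCA and Mt2. MtCA and Mt2 were read as Y244D and Y244A because set 1 has the codes MtCA1, titled Y244D, and Mt1, titled Y244A. That match is an assumption, since neither code recurs exactly. Every allele test was run under both readings, and the comparison of all 6 plasmids with 2 vectors holds under either. Fields that contradict each other leave the construct of these arrays open. The SET deletion array has no set number.

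Tests used limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), using lmFit and eBayes on log2 values, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 8 siRNA arrays formed a single fit. Each gene's spread was therefore shared by both arms, so that an SE or p-value does not measure the spread of 1 arm alone. In the EZH2 arm the titles tie each control to its siRNA array, so that the pair was a block; in the JAK3 arm only numbers are shared, and no block was used. As a check of the EZH2 pairs, deviations of arrays of a pair from their group means correlated with r = -0.086 across genes. The 8 arrays with a vector or a full-length plasmid formed another fit. The 3 comparisons of the siRNA arrays had 3 residual degrees of freedom, the plasmid comparison 6 and the allele comparisons 4.

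Before the data were examined, 27 gene lists were fixed, of which 26 had at least 3 measured genes; the 13 mitochondrial transcripts were not measured by a probe set with 1 symbol. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. Also fixed before the data were examined was the rule for naming genes. It takes JAK3 and EZH2, the 8 largest rises and 8 largest falls among calls, and up to 3 called members of each list that passed, or, where none was called, the 3 with the smallest unadjusted p as values. Where a direction had fewer than 5 calls it takes the 5 genes with the smallest unadjusted p, for alleles the 5 with the smallest larger p of both readings. For the SET deletion it takes 5 genes per direction by the smaller difference from the 2 vectors. Random lists for percentiles numbered 10000.

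The fits were tested on simulated data made from the means and spreads of the real genes with independent errors. In the JAK3 siRNA comparison (14466 genes), 100% of 100 genes changed by 0.5 and 100% of 100 changed by 1 on the log2 scale were recovered, with 15 false calls among 215. In the EZH2 siRNA comparison these shares were 99% and 100%, with 16 false calls among 215. In the plasmid comparison (14410 genes) they were 0% and 60%, with 5 false calls among 65. For Y244D against wild type read by title they were 0% and 0%. Camera called 0 of 26 lists in simulated data without a shift in each of these 4 comparisons. Since the simulated errors were independent between genes, this does not show how often camera errs when the genes of a list vary together.

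Alternatives were quantile normalization, centring each array on its median, no filter and a 50th percentile filter, the mean of a gene's probe sets, and eBayes with trend and robust fitting. Others were array weights, fits of only the arrays compared, adding or removing the block, and leaving out each array in turn. A fit with the interquartile range of each array as a covariate, and set 2 without the array titled Y244A, were added after seeing the data. Every comparison of groups has a side of 2 arrays or 1, so that other splits of the samples, which need 3 or more in each group, were not counted.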

Results

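Transcript levels were measured on 17 arrays of NKYS cells, an established human line of NK/T-cell lymphoma that was grown with interleukin-2, whose receptor signals through the kinase JAK3. The cells were electroporated with siRNAs or plasmids that changed JAK3 or EZH2, the enzyme of Polycomb repressive complex 2 that methylates histone H3. There were 2 arrays with JAK3 siRNA and 2 with a control siRNA for it, and 2 with EZH2 siRNA and 2 with a control siRNA for those. A further 2 arrays had an empty vector, 6 had a full-length EZH2 plasmid and 1 had an EZH2 plasmid without the SET domain, the part that carries the methyltransferase activity. The full-length plasmids were wild type or had a tyrosine changed to aspartate (Y244D) or alanine (Y244A). This tyrosine is a site on EZH2 that JAK3 phosphorylates, aspartate imitates the phosphorylated residue, and alanine cannot carry phosphate. On the 3 full-length plasmid arrays of set 2, the title and the transfection field name different constructs, so that these arrays are named by their title and each allele comparison is given under both readings. The deposited values are linear signal intensities of 28869 probe sets, from 19.39 to 15690, with a median of 60.28 to 72.98 per array. The small number of arrays limits the precision of every value.

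JAK3 siRNA lowered JAK3 itself 2.36-fold. Its signal was 137 ± 0.961 (SD, n = 2) with JAK3 siRNA and 324 ± 2.73 (SD, n = 2) with the control siRNA, a log2 change of -1.24 (SE 0.069; limma, adjusted p = 5.7e-06). Among 14466 genes, 90 rose and 110 fell, but only 5 changed at least 2-fold. The falls were led by FRG2C (log2 change -1.47, SE 0.098), HECW2, an E3 ubiquitin ligase (-1.47, SE 0.153), JAK3, and DUSP6, a phosphatase that turns off ERK (-1.17, SE 0.076). They were followed by the metalloproteases ADAM19 (-0.97) and MMP12 (-0.95), the membrane protein EMP1 (-0.92) and the serotonin receptor subunit HTR3B (-0.89), with adjusted p values from 6.49e-05 to 0.000269. MMP12 was at 39.2 and 35.12 with JAK3 siRNA, near the lower quartile of all signals on these arrays (32.68 and 32.88), so that the size of its fall is uncertain. FRG2C belongs to a family of near-identical copies, which makes its level uncertain, and its signal was 38.71 and 41.11 in the control siRNA arrays of the EZH2 arm against 162.6 and 184.5 in those of the JAK3 arm. A like gap was seen for HTR3B (59.91 and 66.25 against 141.8 and 140.6) and MMP12 (27.62 and 31.86 against 70.1 and 73.36). In these genes the JAK3 siRNA arrays lay closer to the controls of the EZH2 arm than to their own. The controls were closer for DUSP6 (304.4 and 398.2 against 402.6 and 380.7). The rises were led by MINAR2 (log2 change 1.36, SE 0.285, adjusted p = 0.038), the amino acid transporter SLC1A4 (0.96, SE 0.105, adjusted p = 0.000549) and the membrane lectin LAYN (0.85). Next came BCL6, a transcriptional repressor that STAT5 holds down (0.85, SE 0.169, adjusted p = 0.0298), and the microRNA gene MIR21 (0.80, adjusted p = 0.0497). The metallothionein gene MT2A (0.75), the pseudokinase gene TRIB1 (0.75) and the thyrotropin receptor gene TSHR (0.73) followed. MINAR2, BCL6 and MIR21 also varied without JAK3 siRNA. In EZH2 pair 1 they had 1.75, 1.10 and 1.09, and in pair 2 -0.17, 0.07 and -0.05. Their signals on EZH2 control arrays 1 and 2 were 98.48 and 270.6, 117.3 and 192, and 152.9 and 221.9. MT2A (0.04 and -0.05 in the pairs) and TSHR (-0.01 and 0.02) did not vary so. EZH2 had a log2 change of -0.19 (SE 0.088, adjusted p = 0.4), which did not pass.

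Of the 26 gene lists tested after JAK3 siRNA, 5 fell and 0 rose by camera. In the list of interleukin-2 and STAT5 response genes, 2 of 25 measured members rose and 5 fell, with a median log2 change of -0.12 (adjusted p = 0.000996). The falls were DUSP6, the JAK inhibitor SOCS1 (-0.50, SE 0.069), the cytokine oncostatin M, OSM (-0.69, SE 0.103), CISH (-0.51, SE 0.083) and the survival gene BCL2L1 (-0.44, SE 0.076), while BCL6 and DUSP4 (0.45, SE 0.093) rose. CISH, BCL2L1 and DUSP4 are named after their values were seen. Adjusted over the list alone, 2 rose and 9 fell. The list call was lost with an estimated correlation (adjusted p = 0.551).

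In the hypoxia and glycolysis list, 3 of 21 members fell after JAK3 siRNA. They were the pyruvate dehydrogenase kinase PDK1 (-0.38, adjusted p = 0.0193), the collagen hydroxylase subunit P4HA1 (-0.38, adjusted p = 0.0338) and hexokinase 2, HK2 (-0.44, adjusted p = 0.0427). That list had a median of -0.10 (camera adjusted p = 0.001; adjusted p = 0.551 with an estimated correlation), and 3 also fell adjusted over the list alone. All 20 measured ribosome biogenesis genes had values below 0, with a median of -0.20 (camera adjusted p = 1e-07; adjusted p = 0.685 with an estimated correlation). None of them passed over all genes and 8 did adjusted over the list alone, with WDR12 at -0.29, RRP9 at -0.30 and DKC1 at -0.32. DNA replication genes had values below 0 in 31 of 38 members and a median of -0.12 (camera adjusted p = 8.63e-05; adjusted p = 0.685 with an estimated correlation). None passed, either over all genes or adjusted over the list alone, with ORC6 at -0.26, POLD3 at -0.25 and GINS1 at -0.29. Among 18 G1-S regulators E2F7, a repressor of E2F targets, fell (-0.35, adjusted p = 0.0302), 2 fell adjusted over the list alone, and the median was -0.11 (camera adjusted p = 0.00267; adjusted p = 0.685 with an estimated correlation and 0.06 without JAK3 siRNA array 2). The list of natural killer identity and cytotoxicity genes did not pass (adjusted p = 0.872), although its members KLRD1 (-0.47, adjusted p = 0.00991) and NCAM1 (-0.36, adjusted p = 0.0298), fell. Adjusted over the list alone 2 fell and 2 rose, with CD244 at 0.34 (adjusted p = 0.108) and NCR1 at 0.31 (adjusted p = 0.0835) over all genes; these 4 are named after their values were seen. The lists of B cell, monocyte, T cell, and epithelial and fibroblast markers did not pass, with adjusted p values from 0.284 to 0.872. The 200 gene calls became 45 or 33 without JAK3 siRNA array 1 or 2, and 36 or 37 without control array 1 or 2, and 14, 13, 13 and 14 of the 22 called genes taken by the naming rule were kept in these fits. They numbered 94 with no filter on low signal, 523 in a fit of only these 4 arrays and 699 with array weights.

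**Figure D1:**
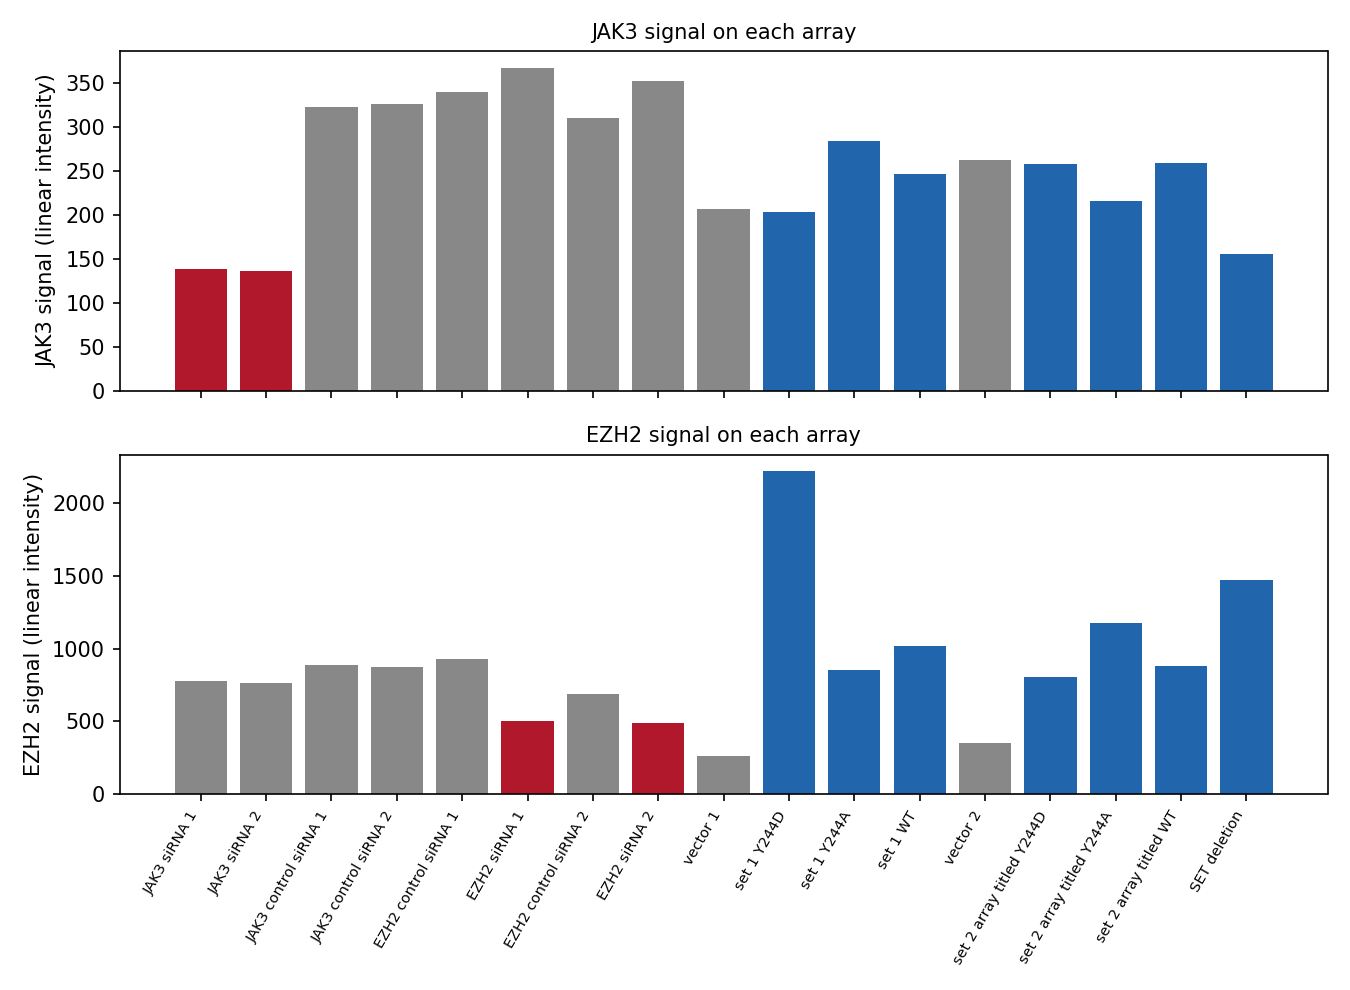
Bars give the linear signal intensity of JAK3 (top) and EZH2 (bottom) on each of the 17 arrays, with the arrays of the siRNA against that gene in red, EZH2 plasmids in blue and all others in grey. JAK3 was 138.1 and 136.7 with JAK3 siRNA, EZH2 was 500.9 and 488.7 with EZH2 siRNA, and the set 1 Y244D array had the highest EZH2 signal, 2221.

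EZH2 siRNA lowered EZH2 1.62-fold, from 809 ± 166 (SD, n = 2) with control siRNA to 495 ± 8.6 (SD, n = 2), a log2 change of -0.69 within pairs (SE 0.088; limma, adjusted p = 0.0275). The fall was -0.89 in pair 1 and -0.50 in pair 2. The control arrays measured 926.3 and 690.8, the siRNA arrays 500.9 and 488.7. In total 54 genes rose and 82 fell, and 1 changed at least 2-fold. The split moved to 47 higher and 33 lower after quantile normalization, and to 31 higher and 161 lower after centring each array on its median. All 136 called genes had the same sign in both pairs, but a call itself favours such genes, so that this is no separate evidence of agreement. Across all tested genes the effects of the 2 EZH2 pairs correlated with r = 0.169. Same-numbered JAK3 siRNA differences correlated with each other at 0.571, and with EZH2 pair 1 at 0.325 and 0.323. The rises were led by ACP3, a prostatic acid phosphatase (1.03, SE 0.196, adjusted p = 0.0444), the axonemal dynein gene DNAI3 (0.84), and ARRDC3, an arrestin-like regulator of receptors (0.81). The interleukin-1 receptor IL1R1 (0.77), the carboxylesterase CES4A (0.76), the costimulatory receptor TNFRSF9 (0.69), the lysosomal enzyme HGSNAT (0.68) and the autophagy gene DRAM1 (0.67) also rose. The falls were led by the B7-family gene HHLA2 (-0.75, SE 0.143, adjusted p = 0.0444), EZH2, the nuclear pore gene NDC1 (-0.62), the RNA-binding protein RBPMS (-0.59) and the splicing factor SNRNP40 (-0.59). The small nucleolar RNA SNORA2B (-0.57), the cytochrome CYB5B (-0.53) and LRRTM3 (-0.52) followed, with adjusted p values of 0.0275 and 0.0444. JAK3 had a log2 change of 0.15 (adjusted p = 0.328), which did not pass. The pairs were unequal, and over the 136 calls the median ratio of the size in pair 2 to that in pair 1 was 0.608. ACP3 was a marked case, with 1.67 in pair 1 and 0.39 in pair 2. Its SE of 0.196 uses the spread of both siRNA arms and does not show how far these 2 pairs lie apart.

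By camera, 7 of 26 lists fell and 6 rose after EZH2 siRNA, and none of the 13 held with an estimated correlation, where the smallest adjusted p was 0.242. The smallest adjusted p was that of DNA replication genes, with a median of -0.24 and values below 0 in 36 of 38 members (adjusted p = 7.72e-16). Of these CDC6, which loads the replicative helicase, fell (-0.43, adjusted p = 0.0341), and 24 fell adjusted over the list alone. All 29 mitosis genes had values below 0, with a median of -0.23 (adjusted p = 1.73e-13). Cyclin A2, CCNA2 (-0.39), and the checkpoint kinase BUB1 (-0.35) fell, both with an adjusted p of 0.0473, and 19 fell adjusted over the list alone. In ribosome biogenesis NOP16 fell (-0.47, adjusted p = 0.0375), all 20 values were below 0, the median was -0.29 (adjusted p = 8.55e-11) and 14 fell adjusted over the list alone. Single members fell in the nucleotide synthesis list (ADSL, -0.41; list adjusted p = 1.32e-05), among G1-S regulators (TFDP1, -0.35; list adjusted p = 0.000333) and in cholesterol synthesis (EBP, -0.38; list adjusted p = 0.0039). Adjusted over the list alone these 3 lists had 7, 5 and 6 falls. Ribosomal protein genes had a median of -0.06 (adjusted p = 0.0383) and no member passed over all genes or over the list alone, with RPS13 at -0.20, RPL22 at -0.23 and RPS24 at -0.18. With an estimated correlation the adjusted p was 0.254 for DNA replication, ribosome biogenesis and G1-S regulators and 0.242 for the other 4.

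Among the rising lists, genes of the ATF4 and ER stress response had a median of 0.20 with 20 of 24 values above 0 (adjusted p = 8.33e-08). The stress transcription factor DDIT3 (0.45, SE 0.086), WARS1 (0.41, SE 0.084) and the serine synthesis enzyme PSAT1 (0.34, SE 0.072) rose, and 11 rose adjusted over the list alone. Of 18 p53 targets, the growth arrest gene GADD45A rose (0.60, SE 0.092, adjusted p = 0.0275), 16 had values above 0, 2 rose adjusted over the list alone, and the median was 0.16 (adjusted p = 3.97e-06). In the NF-kB list the adhesion molecule ICAM1 rose (0.34, adjusted p = 0.0449), 3 rose adjusted over the list alone, and the list had an adjusted p of 0.0297. The JAK-STAT list (adjusted p = 0.00392) had no called member, with IL2RA at 0.29, STAT3 at 0.26 and IL2RG at 0.21, and 2 rose adjusted over the list alone. The list of natural killer identity and cytotoxicity genes (adjusted p = 0.0127) had none either, with perforin, PRF1, at 0.47 (adjusted p = 0.0501), NKG7 at 0.27 and CD244 at -0.27, and 2 rose adjusted over the list alone. Interferon-stimulated genes (adjusted p = 0.0297) had IFI6 at 0.28, IFI27 at 0.21 and RSAD2, whose signals of 34.71 to 42.8 in this arm were near the lower quartile, at 0.21, no call over all genes and 1 adjusted over the list alone. For each of these 6 lists the adjusted p was 0.242 with an estimated correlation. The list of genes reported as silenced by EZH2 had a median of 0.05 over 13 genes (adjusted p = 0.11) and did not pass, nor did the 4 lists of other cell types (adjusted p from 0.0821 to 0.484). The 136 gene calls became 0 without control or siRNA array 1, which leaves pair 2 (1642 and 1637 at an unadjusted p under 0.05, limma), and 1511 without control or siRNA array 2, which leaves pair 1. They were also 0 with no filter on low signal and with array weights (2511 and 1255 at an unadjusted p under 0.05, limma), and 20 without the pairs as a block. Without control or siRNA array 1 all 6 rising list calls were lost (adjusted p from 0.0813 to 0.598) and 7 falling ones were left. Without control array 2 the calls of cholesterol synthesis (adjusted p = 0.0861) and ribosomal proteins (adjusted p = 0.53) were lost, as they were without siRNA array 2 (0.0863 and 0.53), and the NF-kB call was lost without the block (adjusted p = 0.0583). The interferon and ribosomal protein calls were lost after quantile normalization (adjusted p = 0.0569 and 0.0902) and with the 50th percentile filter (0.0644 and 0.114), and the NF-kB and natural killer calls with no filter (0.0688 and 0.0506).

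**Figure D2:**
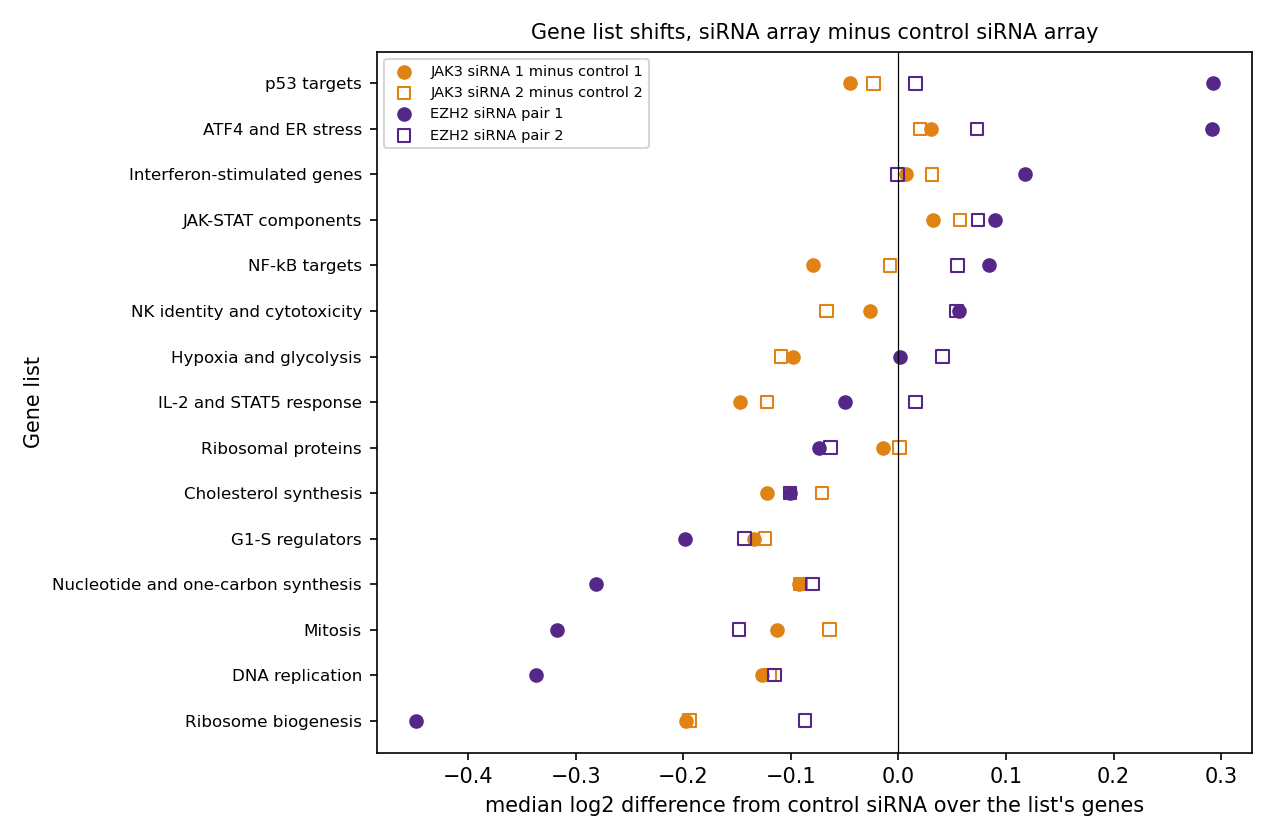
Points give the median log2 difference between siRNA and control siRNA over the genes of each list that passed in either knockdown, separately for the JAK3 siRNA and control arrays of the same number (orange) and the EZH2 siRNA pairs (purple), with number or pair 1 filled and 2 open. Ribosome biogenesis was at -0.20 and -0.19 with JAK3 siRNA, and at -0.45 and -0.09 in EZH2 pairs 1 and 2.

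The 2 knockdowns were compared by testing the difference of their effects, and a gene that did not pass is not shown to move alike in both. That difference passed for 53 genes, 20 with the higher value after JAK3 siRNA and 33 with the higher value after EZH2 siRNA (limma), or 19 and 19 after centring each array on its median. JAK3 and the genes named next were lower after JAK3 siRNA than after EZH2 siRNA. The checkpoint ligand CD274 differed by -1.02 (SE 0.123, adjusted p = 0.00299), the cytokine IL10 by -0.99 (SE 0.118, adjusted p = 0.00299) and TNFRSF9 by -1.10 (SE 0.192, adjusted p = 0.0355). CD274 and IL10 each had -0.86 after JAK3 siRNA, which passed, against 0.17 and 0.13 after EZH2 siRNA, which did not. FRG2C (-1.48), MMP12 (-1.16), the protease inhibitor SERPINB13 (-1.15), DUSP6 (-0.99), GADD45A (-0.74) and PDK1 (-0.56) differed in the same direction. In the other direction stood SNORA2B (0.95, SE 0.116), IRAG2 (0.93), the anthrax toxin receptor ANTXR2 (0.78), the lectin CLEC2D (0.77), MT2A (0.75), GPRIN3 (0.73), TSHR (0.73) and TRIB1 (0.68). In the EZH2 arm FRG2C (38.45 to 41.86), MMP12 (27.62 to 35.77) and TSHR (38.48 to 39.04) had signals near the lower quartile of each array (32.65 to 32.88), so that the size of their difference cannot be read. EZH2 itself differed by 0.50 (SE 0.125, adjusted p = 0.159), which did not pass.

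Of 26 lists, 12 differed between the knockdowns by camera and 0 with an estimated correlation, where the smallest adjusted p was 0.318. The JAK3 minus EZH2 value was above 0 for mitosis (median 0.17, adjusted p = 8.03e-06, BUB1 at 0.32, AURKB at 0.39, PLK1 at 0.43) and DNA replication (0.16, adjusted p = 0.000334, RRM2 at 0.32, POLD3 at -0.23, GINS4 at 0.24). It was also above 0 for nucleotide synthesis (0.13, adjusted p = 0.0267, SHMT1 at 0.41, IMPDH1 at 0.31, CAD at 0.31) and stemness genes (0.10, adjusted p = 0.0216, ABCG2 at 0.33, PROM1 at 0.23, SOX2 at 0.28). No member of these 4 lists passed, and PROM1 (34.94 to 41.5 on the siRNA arrays) was near the lower quartile. It was below 0 for the interleukin-2 and STAT5 response (-0.17, adjusted p = 0.000181), where DUSP6 and TNFRSF9 passed, for hypoxia and glycolysis (-0.12, adjusted p = 0.00079), where PDK1 passed, and for p53 targets (-0.15, adjusted p = 0.000732), where GADD45A passed. ATF4 and ER stress genes had -0.17 (adjusted p = 0.000334), with HERPUD1 at 0.49, WARS1 at -0.51 and PSAT1 at -0.41, none of which passed. NF-kB targets (-0.14, adjusted p = 0.00634, ICAM1 at -0.31, CCL5 at -0.28, NFKBIA at -0.24) and natural killer genes (-0.13, adjusted p = 0.0129, CD244 at 0.60, NCAM1 at -0.45, KLRD1 at -0.41) had no called member. The JAK-STAT list (-0.05, adjusted p = 0.0216) held JAK3 itself as its only call, and apoptosis regulators (-0.06, adjusted p = 0.0216) had BCL2L1 at -0.39, BCL2 at -0.40 and BMF at -0.32, none passing. Adjusted over the list alone, 5 members were lower after JAK3 siRNA in the interleukin-2 and STAT5 list and 3 in the hypoxia list. There was 1 lower member each for p53 targets, the JAK-STAT list and apoptosis regulators, 1 higher and 2 lower for ATF4 and ER stress and for natural killer genes, and 0 for the other 5 lists. Some list differences rested mainly on pair 1 of the EZH2 arm. DNA replication had medians of -0.127 and -0.12 with JAK3 siRNA, but -0.337 and -0.115 in EZH2 pairs 1 and 2. Nucleotide synthesis had -0.092 and -0.091, but -0.281 and -0.08. For p53 targets they were -0.045 and -0.023, but 0.292 and 0.016. The interleukin-2 and STAT5 list differed in both pairs, with -0.147 and -0.122 against -0.05 and 0.016.

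Across 14466 genes the log2 changes of the 2 knockdowns, which have separate controls, correlated with Pearson's r = 0.33. This value has no p because genes are not independent replicates. Both lowered 7 genes, namely ADAM19, LRRTM3, MYBL1, POLR3G, RASGRP1, RBPMS and SERPINB3, where 0.62 are expected from independent lists. Both raised 3, ADGRG1, SMAD3 and SNORA65, where 0.34 are expected. SNORA2B rose with JAK3 siRNA and fell with EZH2 siRNA, and SERPINB13 and SULF1 fell with JAK3 siRNA and rose with EZH2 siRNA. ADGRG1, MYBL1, POLR3G, RASGRP1, SERPINB3, SMAD3, SNORA65 and SULF1 are named after their values were seen, and SERPINB3 has near-identical relatives. The correlation was 0.086 without EZH2 control array 1 and 0.087 without EZH2 siRNA array 1. The 53 differing genes became 20, 15, 14 and 15 without JAK3 siRNA array 1, JAK3 siRNA array 2, JAK3 control array 1 and JAK3 control array 2, and 323 without either array of EZH2 pair 2. They numbered 29 without the block and 15 with no filter on low signal.

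EZH2 plasmids raised the measured EZH2 signal to 1160 ± 538 (SD, n = 6) from 304 ± 64.1 (SD, n = 2) with the empty vector. The log2 difference was 1.85 (SE 0.347), a 3.6-fold higher signal. Against the vector of their own set, the 6 arrays had 2.3- to 8.58-fold more EZH2 signal, the most on the set 1 Y244D array. After adjustment over 14410 genes no gene passed with limma, EZH2 included (adjusted p = 1), and 10 genes had an unadjusted p under 0.05, where 720 are expected by chance. That number was 42 without vector array 1 and 2755 without vector array 2, again with no gene passing. The reported fit had no term for the set, although vector array 2 differed at least 2-fold from vector array 1 in 2178 of 14400 genes. Few low p values in it are therefore no evidence that the plasmids had no effect. With the set as a block no gene passed either. The genes nearest to passing were PCGF6, a Polycomb group protein (0.44, SE 0.152), TMA7 (0.35), STEEP1 (0.39) and AP3S1 (0.46) on the higher side. On the lower side they were CATSPERH (-0.57, SE 0.208), LINC02591 (-0.56), SNORA70E (-0.38), DRC3 (-0.31) and ZNF2 (-0.30). JAK3 was at 0.06 (SE 0.17).

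By camera, 2 of 26 lists were higher with EZH2 plasmids. Ribosomal protein genes had a median of 0.15 with 30 of 32 values above 0 (adjusted p = 4.91e-07), with RPL13 at 0.29, RPS7 at 0.29 and RPL22 at 0.19. Cholesterol synthesis genes had a median of 0.18 with 16 of 17 above 0 (adjusted p = 0.0253), with DHCR7 at 0.33, SQLE at 0.30 and CYP51A1 at 0.23. No member passed over all genes or over the list alone, and both list calls were lost with an estimated correlation (adjusted p = 0.974). Within sets the 2 lists did not keep a direction: ribosomal protein genes had medians of 0.33, 0.53 and 0.35 in set 1 and -0.04, -0.34 and -0.05 in set 2 against the vector of the same set. Cholesterol synthesis genes had 0.26, 0.71 and 0.53 in set 1 and 0.01, -0.16 and -0.15 in set 2. Without vector array 1 cholesterol synthesis turned to -0.38 (adjusted p = 0.00123) and ribosomal proteins to -0.14 (adjusted p = 0.0669). The cholesterol call was lost without the set 2 array titled Y244D, Y244A or WT (adjusted p = 0.235, 0.166 and 0.0844), after centring each array on its median (0.0895) and with the 50th percentile filter (0.0704). Lists called numbered 4 without each of these 3 arrays or vector array 2, and 3 without vector array 1. The sets also differed in the range of their signals. Vector array 2 differed at least 2-fold from vector array 1 in 2178 of 14400 genes, while 1 to 540 genes did so between an EZH2 plasmid array and its own vector.

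**Figure D3:**
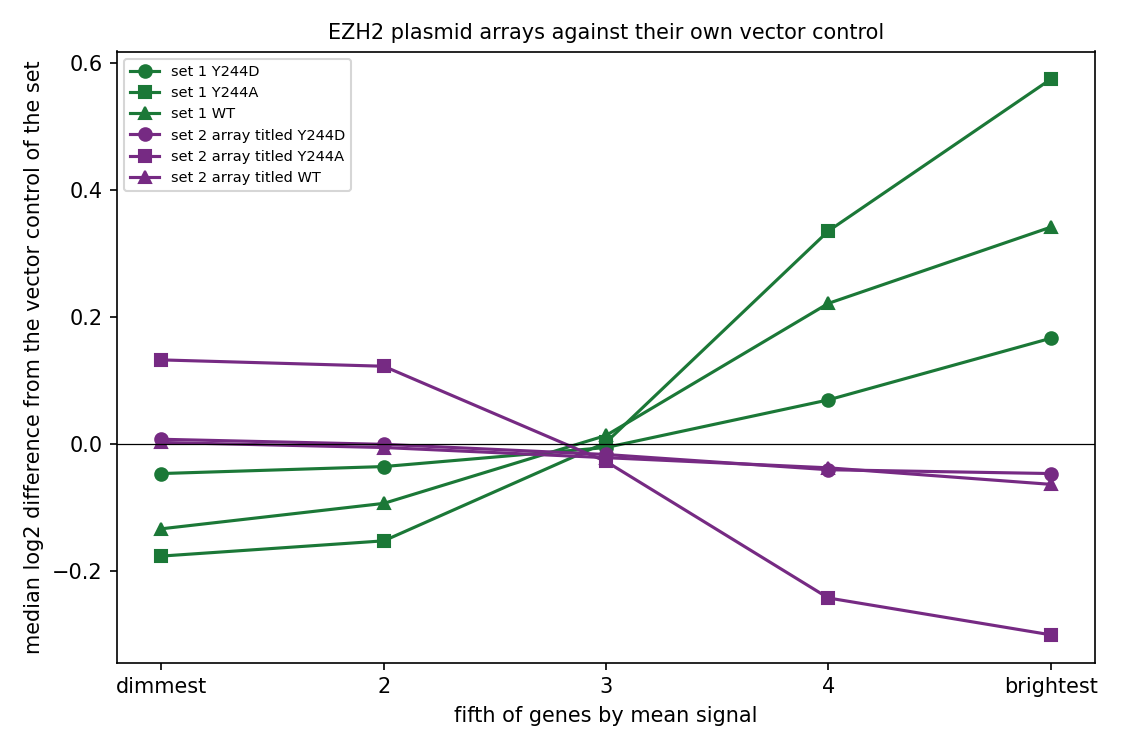
Lines give the median log2 difference of each full-length EZH2 plasmid array from the vector control of its set, for genes in 5 equal bins of mean signal from dimmest to brightest, with set 1 in green, set 2 in purple, and circles, squares and triangles for arrays titled Y244D, Y244A and WT. The brightest bin lay above 0 in the 3 arrays of set 1 (0.17 to 0.57) and below 0 in the 3 of set 2 (-0.05 to -0.30).

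The allele comparisons ask whether this tyrosine of EZH2 matters for what the plasmid does to transcripts. No gene passed between Y244D and wild type or between Y244A and wild type, under either reading of the labels (limma). Read by title, 0 genes had an unadjusted p under 0.05 for Y244D and 5 for Y244A. Read by transfection field, there were 48 for Y244D and 3 for Y244A, against 720 expected by chance in each. With the set as a block these numbers were 39 and 24 by title and 1240 and 84 by transfection field, again with no gene passing. Centring each array on its median moved the median of all genes for Y244D by transfection field from -0.04 to -0.11. The genes lower in Y244D with the smallest p under both readings were SNORD4B (log2 difference -0.73 by either), the costimulatory receptor ICOS (-0.56 by title and -0.63 by transfection field), TIMM8A (-0.63 and -0.70), SNORD37 (-0.80 by either) and SNORD83A (-0.53 and -0.51). Those higher were CLDN11 (0.51 by either), LCE2D (0.49 by either), SERHL2 (0.40 and 0.51), TPRXL (0.47 and 0.43) and MGC34796 (0.43 and 0.45). For Y244A the higher side held ACY3 (0.40 and 0.34), SLC45A4 (0.55 and 0.37), KIF21B (0.32 and 0.31), FBXW4P1 (0.27 and 0.30) and FRMD8 (0.29 and 0.27). The lower side held SNORD77 (-0.48 and -0.41), MARK2P21 (-0.59 and -0.54), SNORA6 (-0.38 and -0.39), RNVU1-3 (-0.50 and -0.37) and OTUD6B (-0.47 and -0.34). None of these 20 genes passed. By camera, 0 of 26 lists differed for Y244D read by title and 6 read by transfection field. The list of epithelial and fibroblast markers was higher, with 6 of 6 values above 0 and a median of 0.26 (adjusted p = 0.0123; adjusted p = 0.695 with an estimated correlation). Mitosis (-0.26), JAK-STAT (-0.24), nucleotide synthesis (-0.20), ribosome biogenesis (-0.24) and ribosomal proteins (-0.15) were lower, with adjusted p values from 0.00173 to 0.0133, and from 0.695 to 0.763 with an estimated correlation. The sets contributed unequally. Against the vector of its set, mitosis had a median of -0.52 on the set 2 array titled Y244A, read there as Y244D, and -0.07 on its wild type partner, but -0.08 and 0.01 on those of set 1. Ribosomal proteins had -0.34 and -0.04 in set 2, and 0.33 and 0.35 in set 1. Nucleotide synthesis had -0.37 and -0.05 in set 2, and 0.01 and 0.12 in set 1. The sets were closer in JAK-STAT genes, with -0.30 and -0.08 in set 2 and -0.01 and 0.23 in set 1. They were also closer in ribosome biogenesis, with -0.34 and -0.01 in set 2 and 0.01 and 0.22 in set 1. So they were in epithelial and fibroblast markers, with 0.38 and 0.01 in set 2 and -0.14 and -0.36 in set 1. Medians on the set 2 array read as Y244D went from 0.13 in the dimmest bin to -0.30 in the brightest. Its wild type partner went from 0.01 to -0.05. In set 1 Y244D went from -0.05 to 0.17 and WT from -0.13 to 0.34. These list shifts may therefore partly follow signal level. Among random lists matched on mean expression, that set 2 array had mitosis at percentile 0 and nucleotide synthesis at 1.38 against its vector. Ribosomal proteins lay at 3 and ribosome biogenesis at 4.74. For Y244A 1 list was lower by title, mitosis (-0.11, adjusted p = 0.00316; adjusted p = 0.941 with an estimated correlation), and 5 were higher by transfection field, mitosis among them (0.26, adjusted p = 3.17e-14; adjusted p = 0.629 with an estimated correlation). The direction of mitosis thus depended on the reading, and by title the sets went opposite ways, at 0.33 on the Y244A array and 0.01 on the WT array of set 1 but -0.52 and 0.11 on those titled so in set 2. By transfection field the sets went the same way, since the set 2 arrays read as Y244A and wild type had 0.11 and -0.07. With an estimated correlation no list differed in any of the 4, where the smallest adjusted p values were 0.939, 0.695, 0.941 and 0.274. In data simulated with independent errors and fitted without the set, no change of 1 on the log2 scale between Y244D and wild type read by title was recovered, so that differences of that size were not detectable in that fit. The fit with the set as a block and the other readings were not simulated.

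The plasmid without the SET domain was measured on 1 array, which gives no spread of its own, and no test was run. The set of this array is not given, so that it was compared with both vectors. EZH2 signal was 1471 on this array, 5.68-fold above vector 1 and 4.21-fold above vector 2, and EZH2 was the only gene at least 2-fold from both vectors in the same direction. The other genes with the largest values above both were MSL3B (log2 difference 1.08 and 0.76), GPSM3 (0.64 and 0.63), OR6K2 (0.62 and 0.67) and SPDYE7P (0.61 and 0.80). Lowest against both were RRM2, a subunit of ribonucleotide reductase (-1.35 and -0.89), MSC (-0.95 and -0.87), DTL, which directs the destruction of the licensing factor CDT1 (-0.96 and -0.79), SLC25A39 (-0.78 and -0.84) and the condensin subunit NCAPH (-0.89 and -0.75). Of 26 lists, those named here were chosen after their values were seen, the first 4 as lists near the same end of the random lists against both vectors. The DNA replication list had medians of -0.25 and -0.54 against vectors 1 and 2, at percentiles 0.01 and 0.06 among 10000 random lists matched on size and mean expression. Mitosis genes had -0.20 and -0.71, at percentiles 3.44 and 0, and G1-S regulators -0.18 and -0.53, at percentiles 2.58 and 0.35. Cholesterol synthesis genes had 0.79 and -0.22, at percentiles 100 and 99. Other lists lay at opposite ends against vectors 1 and 2, among them heat shock and immediate early genes (percentiles 0.03 and 99.2), the interleukin-2 and STAT5 response (0 and 96.8) and epithelial and fibroblast markers (4.29 and 98.8), so that a percentile can depend on the vector. Other single arrays reached the ends as well: mitosis genes lay at percentile 0 in the set 2 array titled Y244A and at 100 in the set 2 array titled WT and in vector 2 against vector 1. Cholesterol synthesis genes lay at 95.5, 97.1 and 99.7 in the set 1 Y244D, Y244A and WT arrays. They lay at 96, 94.6 and 0.03 in the set 2 arrays titled so, and at 99.9 in vector 2 against vector 1. DNA replication genes lay at 0.65 in the set 1 WT array and at 1.93 in the set 2 array titled Y244D. The SET deletion array correlated most closely with the set 2 array titled Y244A (r = 0.991 across probe sets, against 0.969 to 0.978 with the other 7 plasmid and vector arrays). JAK3 was at -0.41 and -0.75. Against a single vector, 88 genes were at least 2-fold away without vector array 1 and 233 without vector array 2.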

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

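Of the tests of outliers and explanations in this part, only those of quantile normalization were written down before their result was seen. By Dixon's criterion for 6 arrays, the EZH2 plasmid arrays were compared in 17 named genes, and chance places about 1 in 20 such groups past it. On the linear scale the set 1 Y244D array stood above the other 5 in EZH2, with a gap of 0.736 of the range, and the set 2 array titled Y244D in RPL22, with a gap of 0.657. On the log2 scale, on which the tests were run, the gaps were 0.624 and 0.619 and no gene passed the criterion.

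The effects of the 2 knockdowns differed in 53 genes by the test of their difference. Named among them were JAK3 (-1.39), FRG2C (-1.48), MMP12 (-1.16), SERPINB13 (-1.15), TNFRSF9 (-1.1), CD274 (-1.02), IL10 (-0.99), DUSP6 (-0.99), GADD45A (-0.74) and PDK1 (-0.56), as log2 values of the JAK3 siRNA effect minus the EZH2 siRNA effect. On the other side were SNORA2B (0.95), IRAG2 (0.93), ANTXR2 (0.78), CLEC2D (0.77), MT2A (0.75), GPRIN3 (0.73), TSHR (0.73) and TRIB1 (0.68). FRG2C, MMP12 and TSHR had signals near the lower quartile of the arrays in the EZH2 arm, so that the size of their difference cannot be read. By camera 12 gene lists differed, some of them mainly in pair 1 of the EZH2 arm, and 0 with an estimated correlation.

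In EZH2 siRNA 12 of the 13 called lists, all but ribosomal proteins, shifted more in pair 1 than in pair 2 by the mean over their genes, and the sum of these means over the 13 was in pair 2 35.8% of that in pair 1. By medians ribosomal proteins had -0.074 and -0.063 and cholesterol synthesis -0.101 in both pairs. Of the summed pair difference 49% lay between the 2 EZH2 siRNA arrays, which enlarged pair 1 in 9 of 13 lists, and the rest between the control arrays, which did so in 12, with mean sizes of 0.0871 and 0.0751 against 0.0217 between the 2 JAK3 siRNA arrays, so that a control array of pair 1 that stood apart stays open. Less EZH2 transcript left in siRNA array 1 is argued against, as its EZH2 signal was 0.04 above that of siRNA array 2, and so are different signal distributions, since pair 2 stayed at 29.6% of pair 1 after quantile normalization. A difference in culture or in the timing of the 2 transfections, and a graded response to EZH2, whose own fall in pair 2 was 56.3% of that in pair 1, stay open and were not tested.

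The brightest of 5 equal bins of genes lay above the vector in every full-length plasmid array of set 1 (mean 0.36) and below it in every one of set 2 (mean -0.14), a difference between the sets that was not tested. The opposite directions rested mainly on the set 2 array titled Y244A, at -0.3 against -0.05 and -0.06 in the others of set 2, and effects of a set 1 and a set 2 array correlated across genes at r = -0.788 to -0.4 in the 3 pairs with it and at -0.211 to -0.08 in the other 6. Different signal distributions are argued against as the whole cause between this array and the set 1 Y244A array, with r = -0.788 as deposited and -0.7 after quantile normalization. They stay open for the other 6 pairs, whose mean r went from -0.155 to -0.069. A vector array of set 1 that stood apart stays open too, since 2 of the 3 set 2 arrays lay within 0.1 of their vector and 1 did not, and an effect of the plasmids, RNA quality and cell survival after electroporation were not tested.

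The JAK3 and EZH2 siRNA effects correlated at r = 0.33 across genes. The listed genes and a shift with signal level do not account for this, since r was 0.33 over the 14037 genes outside the lists and 0.32 after the trend with mean signal was removed. The correlation rested on pair 1 of the EZH2 arm, with r = 0.366 for pair 1 alone and 0.087 for pair 2 alone. A candidate explanation is therefore a state of the pair 1 arrays that resembles the JAK3 knockdown, and a shared response to both knockdowns that was stronger in pair 1 stays open as well.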

How the results depend on the processing

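No list called in either knockdown passed in the other direction under any alternative tried, although the median of the interferon list was -0.001 without EZH2 control array 1, and the numbers of called genes moved widely; where no cause is given, the cause was not tested. Genes changed by JAK3 siRNA numbered 200, and 94 with no filter (more genes tested), 699 with array weights, 523 with only the arrays compared, 104 with the replicate block and 33 to 45 with an array left out. All 104 genes under the block were among the 200; the arrays of the JAK3 arm share only a number, and deviations of same-numbered arrays correlated with r = 0.151. Genes changed by EZH2 siRNA numbered 136 (54 higher, 82 lower), and 80 after quantile normalization (47 higher, 33 lower), 192 after median centring (31 higher, 161 lower), 0 with no filter, 230 with trend and robust fitting, 0 with array weights, 217 with only the arrays compared, 20 without the replicate block and 0 to 1511 with an array left out. Unadjusted p was under 0.05 for 2511 genes with no filter and for 1255 with array weights. The differing genes numbered 53 (20 higher, 33 lower), 38 after median centring (19 higher, 19 lower), 15 with no filter, 29 without the block, 19 with the replicate block in both arms and 14 to 323 with an array left out. Left-out arrays leave an arm with 1 array, which is assumed to vary like the others. Lists called after JAK3 siRNA numbered 5, and 0 with an estimated correlation, 0 with fry and 4 to 6 with an array left out. Those after EZH2 siRNA numbered 13, and 0, 6 (4 of them among the 13) and 7 to 11. The correlation of the effects ranged from 0.086 to 0.366 with an array left out. No alternative gave a called gene for the plasmids or for Y244D or Y244A against wild type, with or without the replicate block; for plasmids and their vectors, 54 genes had an unadjusted p under 0.05 with the block and 915 with the block and the interquartile range of each array, chosen after seeing the data. The 2 plasmid lists became 1 after median centring, 4 with no filter, 0 with an estimated correlation, 0 with fry, 2 to 4 with an array left out, and 0 in set 2 without the array titled Y244A, also chosen after seeing the data. Plasmid values turned without vector array 1 and were highest without vector array 2: JAK3 ranged from -0.112 to 0.235, DHCR7 from -0.35 to 1.004, SQLE from -0.277 to 0.881, CYP51A1 from -0.343 to 0.813, RPS7 from -0.06 to 0.645, cholesterol synthesis from -0.384 to 0.758 and ribosomal proteins from -0.143 to 0.38. In set 2 without the array titled Y244A they turned for JAK3 (-0.022), DHCR7 (-0.039), CYP51A1 (-0.149), RPL13 (-0.075), cholesterol synthesis (-0.079) and ribosomal proteins (-0.049). MARK2P21, Y244A against wild type by transfection field, ranged from -1.111 to 0.041, the latter without the set 1 WT array. For the SET deletion, 2 genes were at least 2-fold from both vectors after median centring and 88 to 233 from a single vector. Fits of only the arrays compared were the reported fits for the differing genes and the plasmids. Dim signals near the background limit what fold changes can show.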

Other observations

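The gene groups in this part were chosen after the gene calls had been seen, so that their p-values are descriptions and not independent evidence. Lysosomal genes were higher after EZH2 siRNA. Of 45 measured genes of lysosomal enzymes and membrane proteins, 7 rose, 0 fell and 40 had values above 0, with medians of 0.23 in pair 1 and 0.11 in pair 2 (camera p = 2.41e-16, p = 0.0344 with an estimated correlation). The 7 were HGSNAT (0.68), the cholesterol carrier NPC2 (0.65), the sialic acid esterase SIAE (0.59), PLD3 (0.49), prosaposin, PSAP (0.46), progranulin, GRN (0.40), and acid alpha-glucosidase, GAA (0.39). The 38 genes without these 7 had a median of 0.12, with 33 above 0 (camera p = 2.47e-10, p = 0.0412 with an estimated correlation). In the opposite direction, all 28 measured proteasome subunits had values below 0 after EZH2 siRNA, with medians of -0.29 in pair 1 and -0.12 in pair 2 (camera p = 3.21e-13, p = 0.111 with an estimated correlation). Of these PSMC6 fell (-0.45, adjusted p = 0.0275). The 27 others had a median of -0.185 (camera p = 3.99e-12, p = 0.126 with an estimated correlation). Both groups went the same way after JAK3 siRNA, with no member called: 35 of 45 lysosomal genes had values above 0 (median 0.06, camera p = 0.000177, p = 0.19 with an estimated correlation) and 27 of 28 proteasome subunits below 0 (median -0.09, camera p = 0.000428, p = 0.358 with an estimated correlation).

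Metallothioneins are small proteins that bind zinc and copper. Genes with metallothionein symbols were taken as a group, pseudogenes such as MT1DP included, and some of them rose after JAK3 siRNA. Of 13 measured genes 9 had values above 0 and 4 below, with a median of 0.14, and 5 rose, namely MT2A (0.75), MT1X (0.59), MT1DP (0.48), MT1G (0.40) and MT1H (0.34), and 0 fell (camera p = 1.05e-08, p = 0.00902 with an estimated correlation). The 8 genes without these 5 had 4 values above 0 and 4 below, with a median of 0.04. By camera they had p = 0.0663, or p = 0.2 with an estimated correlation. The shift of the group thus rested on the 5 called genes. Metallothionein genes have near-identical sequences, so that their probe sets are not independent of each other. After EZH2 siRNA the same 13 genes had a median of 0.02, with none called. Small nucleolar and Cajal body RNAs had a median of 0.14 after JAK3 siRNA, with 125 of 146 values above 0 and 4 calls: SNORA2A (0.40), SCARNA16 (0.39), SNORA2B (0.38) and SNORA65 (0.38) (camera p = 1.68e-17, p = 0.202 with an estimated correlation). The 142 without these 4 had a median of 0.135 (camera p = 7.12e-16, p = 0.227 with an estimated correlation). After EZH2 siRNA the median of all 146 was 0.23 in pair 1 and -0.11 in pair 2.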
